A study of Mus musculus
Rattus norvegicus and Rattus norvegicus and Mus musculus with 18 samples.

How the data were processed

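PolyA libraries were made from tumor core, tumor rim and lung of rats carrying 4T1 tumors (5 each), from normal rat mammary gland (2) and from a 4T1 cell pellet (1). Per the submitters' processing notes, the authors used Trim Galore, STAR, featureCounts and limma with the builds GRCm38 for mouse and Rnor_6.0 for rat; versions, the tool that assigned reads to a species and the strand setting of the counting are not given in the sources used here. For the control libraries, the authors deposited whole read counts per gene of both species (55487 mouse and 32883 rat genes). For the tumor and lung libraries, they deposited 1 table of 17672 mouse genes and 1 of 14876 rat genes (2 without a symbol) holding a normalized signal. Each deposited signal value equals a whole number of reads plus 0.5, times a constant of its library. With this constant, 100% of the values came out as whole reads within 0.01 reads, and the sums of the values differ between libraries, so the values are read here as CPM on the voom scale with a normalization factor per library. Genes with low counts are absent from these tables; the rule for it is not given in the sources used here. The tables of both species were scaled separately, so levels of a mouse and a rat gene are not compared. Columns not mapped to a sample numbered 0. The gland libraries are numbered 1 and 2 as in the deposited table, while the labels number them otherwise, so they are not matched to a label.

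The recovered reads gave the depth of each library and the share of reads on mouse genes, over genes in the tables. Depth was 15346400 to 26669410 mouse reads and 3146720 to 10015352 rat reads per library. Shares in single control libraries carry 95% Clopper-Pearson intervals from scipy 1.17.1, which cover counting error only, since reads without molecular identifiers are not independent molecules. No replicate pair agreed within sampling noise: the lowest chi-square per degree of freedom between replicates was 5.70.

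Before the data were examined, the groups, comparisons, gene lists, the rule for named genes and most alternatives were fixed. The design had assumed counts and the quasi-likelihood test of edgeR. Because the deposited values were a normalized signal, the main test was instead limma 3.58.1 (trend) in R 4.3.3 on log2 of the deposited values, two-sided, with Benjamini-Hochberg adjusted p under 0.05. No pseudocount was added, since 0.5 read is built into the values; a fold change on this scale understates the change of genes with few reads. Genes of at least 1 CPM in at least 5 of the compared libraries were tested. Core and rim were compared in their 10 libraries with the rat as a block, for mouse and for rat genes. Lung and rim were compared for mouse genes in 10 libraries without a block, because Rat3789 gave no rim and Rat3867 no lung. The comparisons of core with rim and of lung with rim share the rim libraries, so their calls are not set against each other. Rat genes of the lung were not tested as a comparison. Limma between the other lungs and the rims only chose the 4113 rat genes of an axis that places the library from Rat3789.

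The pairing of core and rim comes from the animal named in the labels. Deviations of the 2 regions of a rat from their group means correlated across mouse genes at -0.18 (Rat3877), 0.19 (Rat3876), 0.24 (Rat3875), 0.16 (Rat3869) and -0.01 (Rat3867), and across rat genes at 0.34, 0.09, 0.09, 0.03 and 0.03. The core of Rat3876 and the rim of Rat3867 reached 0.30 in mouse genes, above each value within a rat. In rat genes they reached 0.18, which only Rat3877 exceeded. The mouse genes thus do not bear out the pairing. Shares were compared by exact permutation: sign flips of the 5 rat differences for core and rim (32 patterns) and regroupings of the libraries for lung and rim (252).

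Gene lists of at least 4 tested members were tested with camera in limma, with a preset correlation of 0.01, adjusted over the lists of a comparison. Of 17 lists of mouse genes, 12 were called between core and rim; 12 of 25 lists of rat genes were; and 7 of 16 were called between lung and rim. With a correlation estimated from the data, 0 were called in each comparison. The rotation test fry was run beside camera. It asks whether the genes of a list move on balance one way, without comparing them with other genes. Some lists that camera called had fry adjusted p above 0.05. In mouse core and rim they were glycolysis (0.195), integrated stress (0.084), heat shock (0.135), interferon (0.120), inflammatory (0.199) and epithelial (0.061). In rat they were neutrophil (0.067), mast cell (0.087), mitosis (0.067) and inflammatory (0.163). In the lung they were glycolysis (0.074), mitosis (0.126) and replication (0.095). Fry also called the rat angiogenic (0.0122) and mouse alveolar (0.0304) lists. Genes were named by a rule: the 5 largest increases and decreases among called genes of at least 2 mean log2 CPM that moved alike in all rats (core and rim), up to 2 members per list by smallest p, and Angptl7, Mki67, Vegfa and Pecam1, of which Pecam1 was not tested in any comparison. Some genes that this rule selects, and some list members, are not reported here. Other genes are said to have been named after their values were seen, and list members printed without a value were also named then, to complete counts of 5 or fewer.

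The limma test and camera were tested on counts simulated from the real rim means and depths, with about 200 changed genes. The simulation held no effect of the rat. Species assignment, the share tests and the tests of mouse against rat were not simulated, and scaling under broader changes was not tested. For core and rim in mouse (12799 genes) 23.3% of genes changed 1.5-fold, 79.7% of those changed 2-fold and 100% of those changed 4-fold were called, with 11 false among 147 calls. The values were 23.7%, 70.9% and 91.5% with 8 false of 132 for rat (13407 genes), and 50.0%, 79.7% and 100% with 8 false of 156 for lung and rim (12741 genes).

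Alternatives covered relative log expression, upper-quartile and total-count scaling, limma-voom, DESeq2 1.42.0 and edgeR 4.0.16 on the recovered reads, no filter or a mean count of at least 10, an added 1 CPM, removal of genes above 10% of the other species' control or, in the lung, under 5% of the rat count of the same symbol, thinning to the lowest total, removal of a trend with transcript length and GC in mouse, the block, and leaving out each rat or library. Those on edgeR, the added 1 CPM, total-count scaling, length and GC, complete rats only, and Rat3876 and Rat3877 together were added after seeing the data. Mouse positions come from a GENCODE annotation of GRCm38; rat positions were not used here. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.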

Results

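Gene expression was measured by polyA RNA-seq in tissue of immunodeficient SRG rats that carried tumors of 4T1 cells, a metastatic mouse mammary carcinoma line, in the mammary fat pad. Because the cancer cells were mouse and the host was rat, reads assigned to mouse genes stand for tumor cells and reads assigned to rat genes for the host. Tissue was taken on day 27. Each primary tumor was separated into its necrotic core and the non-necrotic rim around it, giving 5 core and 5 rim libraries from the same 5 rats. Another 5 libraries came from lungs, of which 4 shared a rat with a rim and 1 came from Rat3789, which gave no tumor library used here. Normal rat mammary gland (2 libraries) and a pellet of cultured 4T1 cells (1 library) served as controls of a single species. The tumor and lung libraries held between 15346400 and 26669410 mouse reads and between 3146720 and 10015352 rat reads assigned to genes. The gland libraries held 21067626 and 21816039 assigned reads and the pellet 29659780.

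The single-species controls address how well reads were assigned to their species. In the gland, 1.78% of assigned reads fell on mouse genes in library 1 (95% Clopper-Pearson interval 1.77 to 1.79%) and 1.96% in library 2 (1.96 to 1.97%). In the 4T1 pellet, 0.718% fell on rat genes (0.715 to 0.721%). These intervals cover counting error only. The tumor libraries held more mouse than rat reads, so at the pellet rate wrongly placed reads form a larger part of their rat reads. That part is larger in the core, with a mean of 3.60e+06 rat reads, than in the rim, with 5.93e+06. The wrongly placed reads of the gland were led by muscle genes: mouse Atp2a1, a calcium pump of fast muscle, took 8.71% of them in library 1 and 8.03% in library 2. The gland libraries themselves were rich in skeletal muscle transcripts, with the fast myosin Myh4 at 8.81% and 6.41% of their rat reads. Of the mouse genes described below, Angptl7 had 2 mouse reads in each gland library and 2 in the pellet, and Postn had 50 and 61 in the gland libraries and 65 in the pellet.

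Mouse reads made up most of the assigned reads in the core, the rim and the lung. The mouse share of assigned reads was 85.7 ± 1.51% in the core, 77.3 ± 6.51% in the rim and 70.6 ± 4.85% in the lung (SD, n = 5 each). The core exceeded the rim in 5 of 5 rats, by 8.44 points on average (SD of the differences 6.97). An exact two-sided sign-flip test gave p = 0.0625, the smallest value this test can give with 5 pairs, so it cannot reach 0.05; an exact unpaired permutation test gave p = 0.00794. The difference in Rat3876 was 20.7 points, against 4.19 to 7.26 in the other rats, and without it the mean was 5.37. The lung lay below the rim on average (lung minus rim -6.69 points; exact two-sided permutation test, p = 0.127, n = 5 each), and with 1 rat left out the difference ranged from -4.44 without Rat3877 (exact p = 0.371) to -8.69 without Rat3876 (exact p = 0.0286). In the 4 rats that gave both, the lung lay above the rim in Rat3876 and below it in the other 3 (mean -6.96, exact paired p = 0.25).

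**Figure D1:**
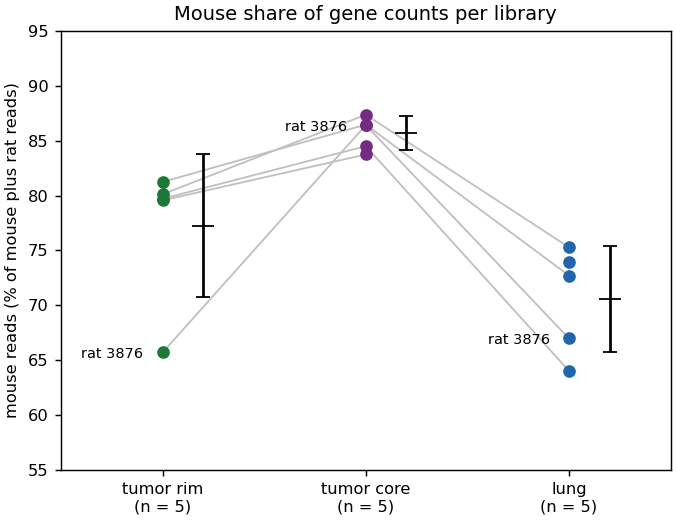
Share of assigned reads that fell on mouse genes (percent) in each rim, core and lung library, with lines joining libraries of the same rat and the mean ± SD beside each group (n = 5). The cores lie between 83.8 and 87.4%, and the rim of Rat3876 lies lowest among the rims at 65.7%.

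The first comparison asks how 4T1 cells in the necrotic core differ from those in the rim. Angptl7, a secreted angiopoietin-like protein, stood at 61.3 ± 35.5 CPM in the core and 1.71 ± 0.605 CPM in the rim (SD, n = 5 each), 33.7-fold higher (log2 difference 5.07 ± 0.30 SE, limma adjusted p = 0.000318). It was higher in the core in 5 of 5 rats. Postn, the matrix protein periostin, rose from 19.9 ± 9.20 to 942 ± 471 CPM (5.65 ± 0.53, adjusted p = 0.000723), and Dcn, the proteoglycan decorin, from 1.54 ± 1.23 to 68.6 ± 54.4 CPM (5.47 ± 0.55). The complement gene C4b (4.34 ± 0.31) and the noradrenaline transporter Slc6a2 (3.96 ± 0.40) completed the 5 largest increases among genes of at least 2 mean log2 CPM that moved alike in all 5 rats. The basal keratin Krt14 fell from 113 ± 58.3 CPM in the rim to 5.97 ± 2.45 in the core (-3.98 ± 0.53, adjusted p = 0.00263), and the gelatinase Mmp9 from 405 ± 250 to 24.6 ± 8.75 CPM (-3.85 ± 0.29). The laminin chain Lamb3 (-3.38 ± 0.28), the 14-3-3 protein gene Sfn (-2.84 ± 0.20) and Acap1 (-2.80 ± 0.17) were the next largest decreases.

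Of 13070 mouse genes tested, 2585 differed between core and rim, 1326 higher and 1259 lower in the core, and 472 and 355 of these differed by at least 2-fold. With total-count scaling the split was 1139 higher to 1515 lower, and with upper-quartile scaling 1255 to 1367. Of the 2585, 2377 moved the same way in all 5 rats. Without Rat3875, 1260 genes were called, and without Rat3867, 1360. Mitochondrially encoded genes took 2.08 ± 0.304% of mouse reads in the core and 1.78 ± 0.112% in the rim (SD, n = 5 each). Angptl7 lies on mouse chromosome 4 (148495183 to 148500460, GRCm38, minus strand) inside Mtor on the opposite strand, and as the strand setting of the counting is not given in the sources used here, part of its reads cannot be placed with certainty. C4b on chromosome 17 (34728380 to 34743882) overlaps no other annotated gene but has a near-identical neighbor, so its level is uncertain. Postn lies on chromosome 3 (54361109 to 54391037), Krt14 on chromosome 11 (100203162 to 100207548) and Mmp9 on chromosome 2 (164940780 to 164955850), none overlapping another annotated gene. Lamb3 on chromosome 1 (193207699 to 193343878) overlaps genes on both strands, so its level is uncertain too.

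**Figure D2:**
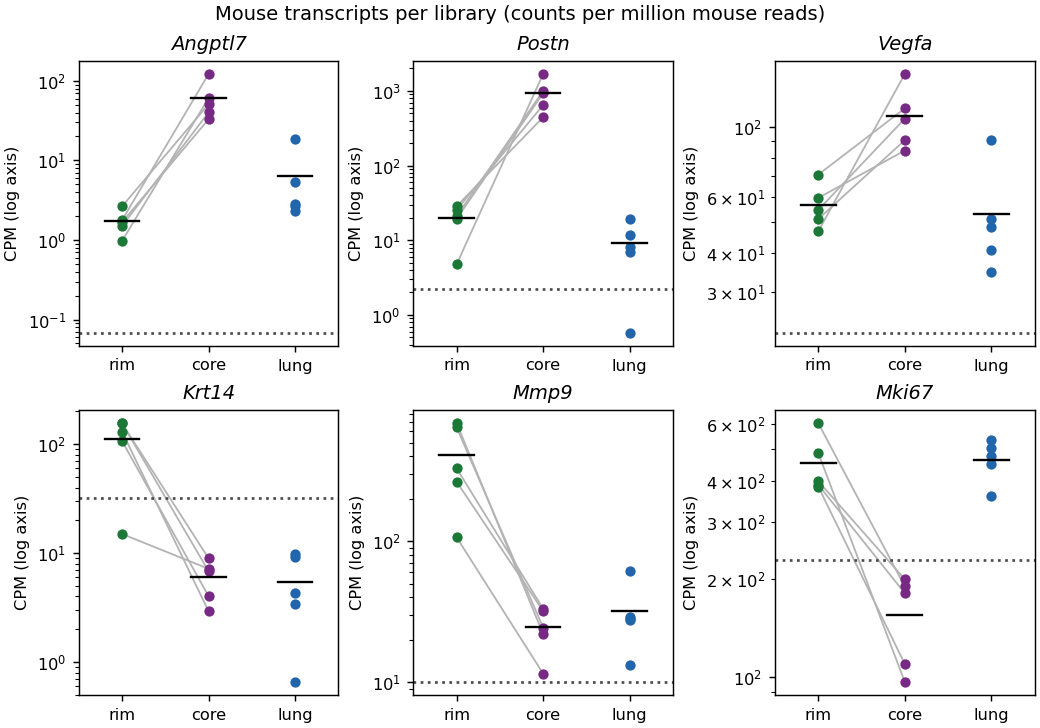
CPM on a log axis of 6 mouse genes in each rim, core and lung library, with lines joining the rim and core of a rat, bars at the group mean and a dotted line at the value in the 4T1 pellet. Angptl7 averaged 61.3 CPM in the core against 1.71 in the rim, while Krt14 averaged 5.97 against 113.

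Transcripts of dividing cells were lower in the core. All 20 genes of the G2 and mitosis list fell (20 adjusted over the list alone), with a median log2 difference of -1.11. The proliferation marker Mki67 went from 453 ± 93.6 to 156 ± 48.4 CPM (-1.58 ± 0.18, adjusted p = 0.00157), and Cenpf (-1.43) and Plk1 (-1.33) moved alike. Of 20 DNA replication genes, 16 fell, 0 rose and 4 were not called (18 lower adjusted over the list alone), among them Rrm2 (-1.62) and Rrm1 (-0.98), which encode ribonucleotide reductase. Cholesterol synthesis genes were also lower: 16 of 19 fell and 3 were not called (18 lower adjusted over the list alone), with Hmgcs1 at -1.20 and Cyp51 at -1.37. These 3 lists had camera adjusted p = 9.88e-16, 3.30e-11 and 3.86e-11. For each of them, adjusted p = 0.304 with an estimated correlation.

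Genes of the hypoxia response were higher in the core, 13 of 23, with 0 lower and 10 not called (15 higher adjusted over the list alone; median 0.62; camera adjusted p = 1.19e-08, adjusted p = 0.304 with an estimated correlation). Vegfa, the vascular growth factor, rose from 56.6 ± 9.19 to 109 ± 24.7 CPM (0.93 ± 0.16, adjusted p = 0.00584), and P4ha1 (0.95) and Higd1a (1.10) rose as well. Glycolysis genes were divided: Hk2 and Eno2 (1.27) rose, Aldoc fell (-0.84) and 13 of 16 were not called (2 higher and 1 lower adjusted over the list alone). That list had camera adjusted p = 0.0417, and adjusted p = 0.547 with an estimated correlation. Its call ended without Rat3876, Rat3875 or Rat3867 (adjusted p = 0.0652, 0.0747 and 0.196), without genes above 10% of the other species' control (0.117) and with a length and GC trend removed (0.0813; 0.00659 to 0.196 over all alternatives), and Eno2 was not called without Rat3876 and Rat3877 (adjusted p = 0.0647).

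Some stress genes rose in the core. Of 19 genes of the integrated stress and unfolded protein response, 8 rose and 11 were not called (8 higher adjusted over the list alone; camera adjusted p = 0.000283, adjusted p = 0.304 with an estimated correlation), including Cebpb (1.44), Ppp1r15a (1.70) and Ddit3 (1.76), the last named after its values were seen. Of 11 heat shock genes, 4 rose and 7 were not called (5 higher adjusted over the list alone; camera adjusted p = 0.00228, adjusted p = 0.478 with an estimated correlation): Hspb1 (3.05 ± 0.62), Hspa1b (2.35 ± 0.50), Dnajb1 and Chordc1. Hspa1b has a near-identical copy and its level is uncertain. Of 11 inflammatory genes, Cxcl5 (1.97), Ptgs2 (1.57) and Ccl2 (3.55) rose and 8 were not called (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0446, adjusted p = 0.547 with an estimated correlation). The inflammatory call ended without Rat3869 (adjusted p = 0.0924) or Rat3867 (0.195), with no filter (0.0545), with a mean count of at least 10 (0.0524), without genes above 10% of the other species' control (0.113) and with a length and GC trend removed (0.0522), with a range of 0.0106 to 0.195 over all alternatives. Of 18 interferon response genes, Irf7, Oas1a, Ddx58 (-0.51) and Ifih1 (-0.77) fell and 14 were not called (4 lower adjusted over the list alone; camera adjusted p = 0.0183, adjusted p = 0.478 with an estimated correlation). That call ended without Rat3867 (adjusted p = 0.0534) or without Rat3876 and Rat3877 together (0.150; from 0.000313 over all alternatives). Ddx58 was not called without the pairing by rat (adjusted p = 0.0752) or without Rat3876 and Rat3877 together (0.0778), and Ifih1 was not called without Rat3875 or Rat3867 (up to 0.0694).

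Several epithelial genes were lower in the core and several mesenchymal and angiogenic genes higher. Of 18 epithelial junction and keratin genes, 9 fell, 8 were not called and Ocln rose (1 higher and 10 lower adjusted over the list alone; median -0.69; camera adjusted p = 3.16e-05, adjusted p = 0.304 with an estimated correlation). Ocln, a tight junction gene named after its values were seen, differed by 0.58 and was not called without Rat3875 or Rat3867 (adjusted p up to 0.0645). The rim of Rat3877 stood lowest among the rims for this list and for the mesenchymal list, at means of 6.05 and 6.72 log2 CPM. Of 16 mesenchymal genes, 6 rose, including Postn and Twist1 (1.39), Tgfbi (-1.13) and Inhba (-0.82) fell and 8 were not called (8 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.0446, adjusted p = 0.304 with an estimated correlation). The mesenchymal call ended without Rat3875 (adjusted p = 0.0745) or Rat3867 (0.0534) and with a length and GC trend removed (0.0819), with a range of 0.0245 to 0.0819 over all alternatives, and Inhba was not called without Rat3876, Rat3869 or Rat3867 (adjusted p up to 0.0695). Of 14 angiopoietin-like and angiogenic genes, Angptl7, Angptl6, Angpt1 (2.22), Vegfa and Vegfc (2.36) rose, Pdgfb fell and 8 were not called (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0227, adjusted p = 0.304 with an estimated correlation). Tgfbi, Inhba, Vegfc and Ccl2 were named after their values were seen.

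**Figure D3:**
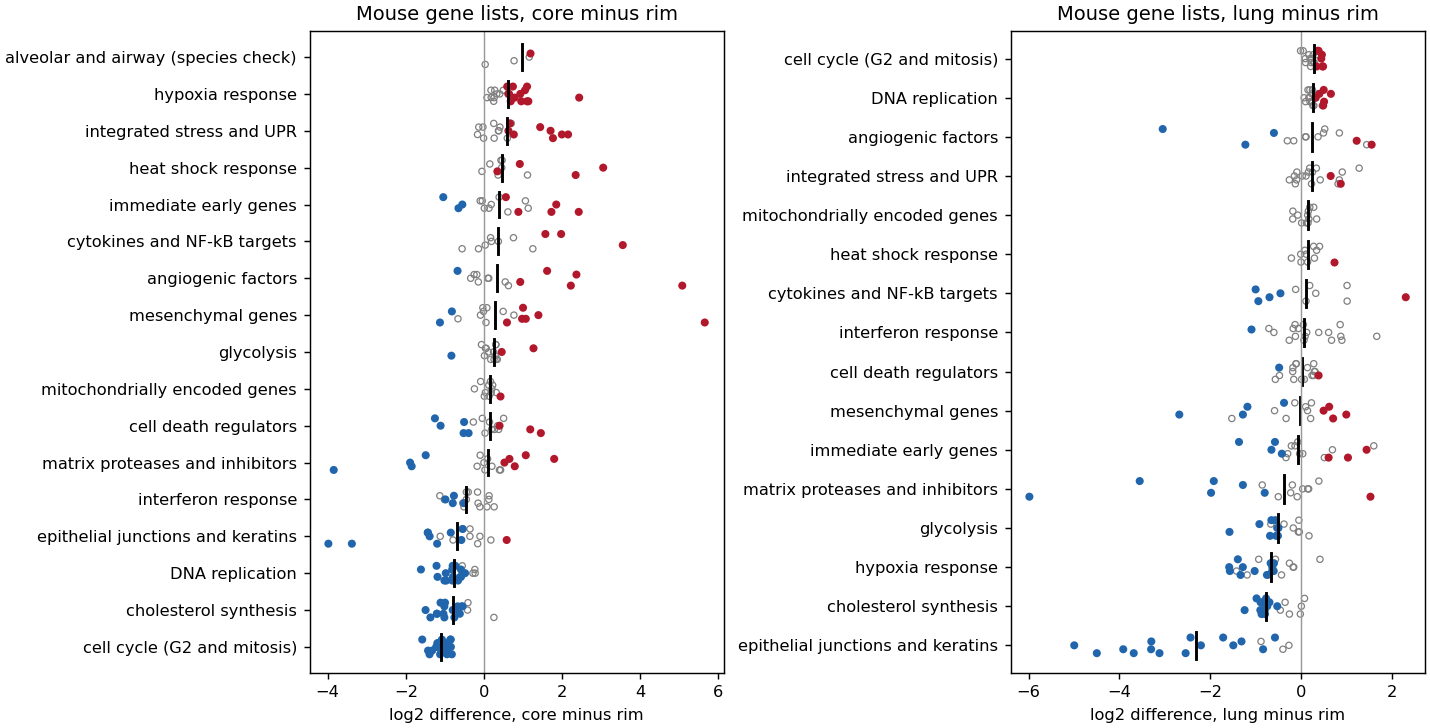
Log2 differences of mouse genes for each gene list, core minus rim and lung minus rim, where each point is a list member, filled where called higher (red) or lower (blue) and open where not called, and a black bar marks the median. In the core all 20 members of the G2 and mitosis list are called lower, and in the lung 15 of 18 epithelial members are.

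The second comparison asks how the rat host tissue differs between core and rim. By the same rule, the genes with the largest rises in the core were inducible nitric oxide synthase Nos2, from 2.06 ± 0.882 to 38.4 ± 27.4 CPM (4.13 ± 0.39, adjusted p = 0.000188), and Spp1, the secreted protein osteopontin, from 402 ± 245 to 4956 ± 1061 CPM (3.80 ± 0.23, adjusted p = 7.01e-05). They were followed by Acod1 (3.72 ± 0.44), which makes itaconate in activated macrophages, the neutrophil chemokine Cxcl2 (3.66 ± 0.52) and the receptor Hcar2 (3.45 ± 0.48). The secreted Wnt modulator Sfrp4 fell from 592 ± 582 to 6.11 ± 7.92 CPM (-6.84 ± 0.68, adjusted p = 0.000224). The lymphoid chemokines Ccl21 (-6.66 ± 0.63) and Cxcl13 (-6.44 ± 0.81), Sfrp2 (-5.71 ± 0.74) and C4b (-5.67 ± 0.41) fell with it. All 10 genes moved the same way in 5 of 5 rats. Sfrp4 had 26 rat reads in the 4T1 pellet, so its low level in the core is uncertain.

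Of 13559 rat genes tested, 5092 differed, 2373 higher and 2719 lower in the core, and 476 and 1634 of these differed by at least 2-fold. Without Rat3876 and Rat3877 together, 3392 were called. Without genes above 10% of the other species' control, 12139 rat genes were tested and 4790 called. Rims of these rats held more of the host epithelial gene Krt8 (54.0 and 58.1 CPM against 2.72 to 6.04) and of Adipoq (117 and 32.6 CPM against 2.34 to 5.94) than other rims, but the basal keratin Krt14 was highest in the rim of Rat3867, at 208 CPM against 31.9 in Rat3876 and 21.1 in Rat3877. The rat tables are shallower than the mouse tables, with 3146720 to 9183248 rat reads per tumor library, and rat gene positions were not used here. Mitochondrially encoded genes took 2.84 ± 0.303% of rat reads in the core and 2.31 ± 0.207% in the rim (SD, n = 5 each).

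Many stromal cell markers were lower in the core. All 13 fibroblast and collagen genes fell (13 adjusted over the list alone; median -2.82; camera adjusted p = 2.04e-09, adjusted p = 0.465 with an estimated correlation). Among them were Thy1 (-2.76), Mmp2 (-2.82) and, named after its values were seen, Col1a1, from 21328 ± 6082 to 4010 ± 2076 CPM (-2.55 ± 0.31). Of 13 pericyte and smooth muscle genes, 6 fell and 7 were not called (7 lower adjusted over the list alone; camera adjusted p = 0.0074, adjusted p = 0.465 with an estimated correlation), with the platelet-derived growth factor receptor Pdgfrb at -1.51 and Notch3 at -1.49. Of 7 lymphatic genes, 6 fell and 1 was not called (6 lower adjusted over the list alone; camera adjusted p = 0.00224, adjusted p = 0.477 with an estimated correlation). Pdpn (-3.05) and Lyve1 (-4.06) were among those that fell, and the receptor Flt4 was not called (0.52, adjusted p = 0.141) except as higher without Rat3876 (0.84, adjusted p = 0.00659) or without Rat3876 and Rat3877 together (0.83, 0.0284), against the direction of the other members; Lyve1 and Flt4 were named after their values were seen. The endothelial list was not called (camera adjusted p = 0.329): Plvap (-1.06), Tek (-0.84) and Emcn fell and 11 of 14 were not called (3 lower adjusted over the list alone). Adipoq, an adipocyte transcript that was uneven between rims, differed by -2.20 and was not called (adjusted p = 0.0727), but was called by limma-voom (-3.41, adjusted p = 0.0077), by edgeR (-2.63, 0.0463) and without Rat3875 (-2.95, 0.0303), with differences of -3.41 to -0.37 over all alternatives.

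Myeloid markers divided. Of 16 macrophage and monocyte genes, 9 rose, 4 fell and 3 were not called (10 higher and 4 lower adjusted over the list alone), and the list was not called (camera adjusted p = 0.0608; median 0.41, mean -0.11). Cd68, a lysosomal protein of macrophages, rose from 251 ± 46.7 to 525 ± 100 CPM (1.06 ± 0.08), while the scavenger receptor Cd163 fell from 1695 ± 779 to 156 ± 133 CPM (-3.71 ± 0.50), as did Adgre1, Mrc1 and Ms4a7 (-2.89). The macrophage call was gained without Rat3875 (adjusted p = 0.0178), by limma-voom (0.0495) and with no filter (0.0469; 0.0178 to 0.299 over all alternatives). Of 10 neutrophil genes, 5 rose and 5 were not called (7 higher adjusted over the list alone; camera adjusted p = 0.0132, adjusted p = 0.639 with an estimated correlation). Among them were Cxcr2 (1.23), Csf3r, S100a8 (1.89) and S100a9 (2.38), the last 3 named after their values were seen. Of 10 mast cell genes, Hdc (-3.86), Cma1 (-4.53), Cpa3 and Mcpt1l1 fell and 6 were not called (4 lower adjusted over the list alone; camera adjusted p = 0.0241, adjusted p = 0.639 with an estimated correlation). The mast cell call ended without Rat3877 (adjusted p = 0.0547) or Rat3876 (0.131), without both (0.521) and without genes above 10% of the other species' control (0.160), with a range of 0.00341 to 0.521 over all alternatives.

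Many inflammatory, metabolic and heat shock genes of the host were higher in the core and many interferon genes lower. Of 17 inflammatory genes, 8 rose, Il6 (-2.93) and Lif (-1.82) fell and 7 were not called (10 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0126, adjusted p = 0.639 with an estimated correlation), with the chemokine Ccl3 at 3.35. Lif was named after its values were seen. Hypoxia genes rose in 14 of 22 cases, P4ha2 fell (-0.62) and 7 were not called (15 higher and 2 lower adjusted over the list alone; camera adjusted p = 5.04e-05, adjusted p = 0.465 with an estimated correlation), with Hilpda at 1.77 and Bnip3 at 1.26. P4ha2, named after its values were seen, was not called without Rat3876 and Rat3877 (adjusted p up to 0.0841). Of 15 glycolysis genes, 12 rose and 3 were not called (12 higher adjusted over the list alone; camera adjusted p = 1.15e-06, adjusted p = 0.465 with an estimated correlation), including the lactate transporter Slc16a3 (1.29) and Gpi (1.21). All 11 heat shock genes rose (11 adjusted over the list alone; camera adjusted p = 8.21e-06, adjusted p = 0.477 with an estimated correlation), with Hspa1b at 3.20 and Hspd1 at 0.92. Of 20 interferon response genes, 15 fell, Ifit1 (1.66) and Ifit3 (0.91) rose and 3 were not called (15 lower and 2 higher adjusted over the list alone; camera adjusted p = 3.45e-05, adjusted p = 0.465 with an estimated correlation). Ifit2 (-1.27) and Cxcl10 (-2.31) were among those that fell. Ifit1 and Ifit3 were named after their values were seen; Ifit1 was not called without Rat3877, Rat3876, Rat3869 or Rat3867 (adjusted p up to 0.117) or without Rat3876 and Rat3877 together (0.220), and Ifit3 was not called without the pairing by rat (adjusted p up to 0.145).

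Division and matrix genes of the host also differed. Of 19 G2 and mitosis genes, 12 rose and 7 were not called (12 higher adjusted over the list alone; camera adjusted p = 0.000104, adjusted p = 0.639 with an estimated correlation). Aurkb rose by 1.26 and Birc5 by 0.82 on the log2 scale. Mki67 stood at 182 ± 33.5 CPM in the rim and 288 ± 66.4 in the core (0.65 ± 0.18, adjusted p = 0.0244, higher in 4 of 5 rats), and was not called without Rat3876, Rat3875 or Rat3867 (adjusted p up to 0.0830) or without Rat3876 and Rat3877 together (0.124). Of 20 matrix protease and inhibitor genes, 12 fell, Mmp12 (1.80) and Plau (1.58) rose and 6 were not called (12 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.00821, adjusted p = 0.465 with an estimated correlation), with Adamts5 at -1.92. Mmp12 and Plau were named after their values were seen. The angiogenic list was not called (camera adjusted p = 0.426), with Vegfb, Pdgfa and Apln higher, Angptl2 (-2.47), Angptl1 (-4.46), Angpt1, Vegfd (-3.60) and Fgf2 lower and 8 of 16 not called (3 higher and 5 lower adjusted over the list alone). Rat Angptl7 was low in both regions, 0.95 ± 0.686 CPM in the core and 2.89 ± 1.80 in the rim, and was not called (-1.76 ± 0.78, adjusted p = 0.112), except without Rat3876 (adjusted p = 0.0485; up to 0.305 over all alternatives). Rat Vegfa did not pass the test either (-0.18, adjusted p = 0.353).

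**Figure D4:**
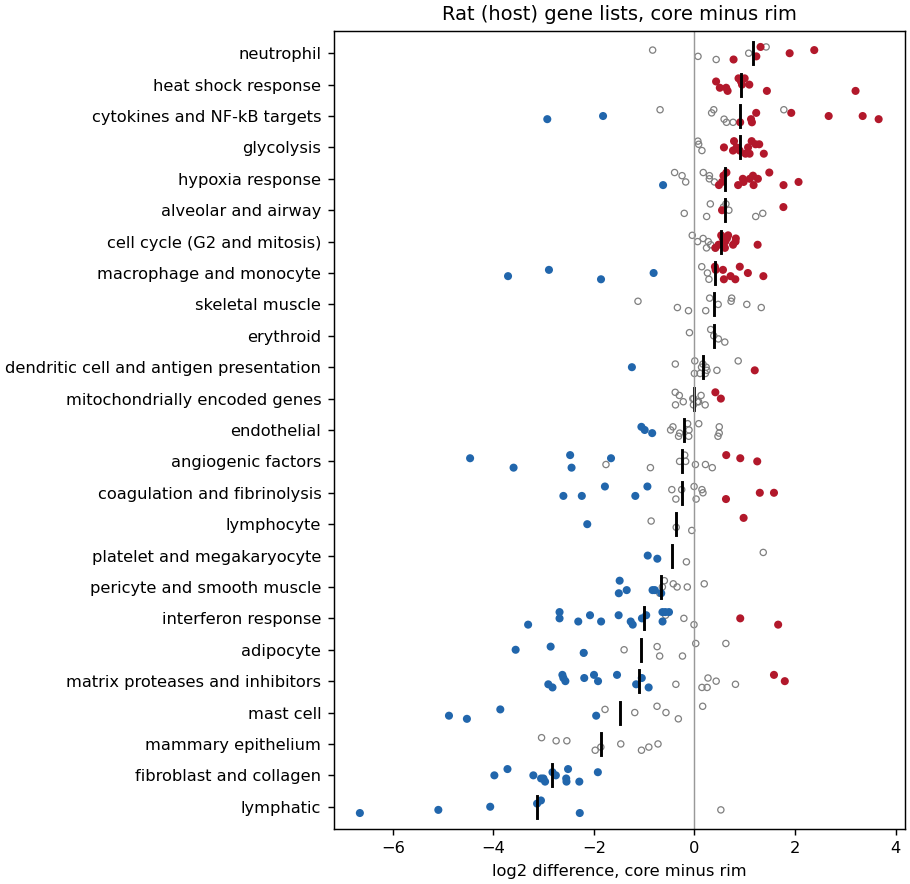
Log2 differences of rat genes, core minus rim, for each gene list, where each point is a list member, filled where called higher (red) or lower (blue) and open where not called, and a black bar marks the median. All 13 fibroblast and collagen members are called lower and all 11 heat shock members higher.

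The third comparison asks how 4T1 cells in the lung differ from those in the tumor rim. Among genes of at least 2 mean log2 CPM, the largest increases in the lung were Rcan2, a calcineurin regulator, from 1.21 ± 0.803 to 25.1 ± 10.6 CPM (4.71 ± 0.59, adjusted p = 0.000568), the cell adhesion gene Nrcam (4.47 ± 0.49), Thsd4 (3.87 ± 0.42), Camk1d (3.61 ± 0.28) and Phex (3.47 ± 0.57). The collagenase Mmp13 fell from 111 ± 66.4 to 1.52 ± 0.861 CPM (-5.98 ± 0.64, adjusted p = 0.000274). The tight junction gene Cldn4 went from 322 ± 212 to 9.19 ± 5.97 CPM (-4.99 ± 0.61), and Krt14 (-4.50 ± 0.78), Tnik (-4.48 ± 0.56) and Anxa8 (-4.10 ± 0.58) fell as well. Angptl7 averaged 6.34 ± 6.91 CPM in the lung and 1.71 ± 0.605 in the rim. The lung mean was carried by the library from Rat3789, at 18.5 CPM against 2.30 to 5.37 in the other lungs. The gene was not called by limma (1.45 ± 0.51, adjusted p = 0.0637), but was called by DESeq2 (adjusted p = 0.00354) and edgeR (0.0395), with values up to 0.140 over all alternatives. Mki67 (0.05, adjusted p = 0.833) and Vegfa (-0.16, adjusted p = 0.646) did not pass the test.

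Of 12970 mouse genes tested, 2603 differed, 1285 higher and 1318 lower in the lung, and 224 and 406 of these differed by at least 2-fold. With total-count scaling the split was 1717 higher to 1108 lower, that is 60.8% higher against 49.4%. Without the lung of Rat3877, 1589 genes were called. The species check lists had 3 and 1 tested members here, too few for a test, and no control was rat lung. Without genes under 5% of the rat count of the same symbol, 98.8% of the calls stayed. Nrcam was lowest in the lung of Rat3789, at 2.82 log2 CPM against 4.35 or more, and that library had few alveolar host transcripts. Whether rat reads add to it in the other lungs was not tested. Mmp13 lies on chromosome 9 (7272514 to 7283331, GRCm38) and Cldn4 on chromosome 5 (134945119 to 134946934), neither overlapping another annotated gene.

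The epithelial list was the one with the largest decrease among the lists tested in the lung. Of its 18 genes, 15 fell and 3 were not called (16 lower adjusted over the list alone; median -2.32; camera adjusted p = 1.07e-13, adjusted p = 0.212 with an estimated correlation). The adhesion molecule Epcam went from 508 ± 187 to 59.1 ± 28.7 CPM (-3.11 ± 0.32), and the junction gene Jup from 254 ± 87.5 to 45.9 ± 11.2 CPM (-2.43 ± 0.23). E-cadherin, Cdh1 (-2.54), fell too and was named after its values were seen. Of 16 matrix protease genes, 6 fell, including Plau (-1.98), Plat rose (1.53) and 9 were not called (1 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.00669, adjusted p = 0.432 with an estimated correlation). Plat was named after its values were seen.

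Many hypoxia, glycolysis and cholesterol synthesis genes were lower in the lung than in the rim. Of 23 hypoxia genes, 12 fell and 11 were not called (18 lower adjusted over the list alone; camera adjusted p = 2.66e-07, adjusted p = 0.432 with an estimated correlation), with the stress gene Ddit4 at -1.33 and P4ha2 at -1.02. Of 16 glycolysis genes, 9 fell and 7 were not called (9 lower adjusted over the list alone), with Aldoc at -1.57 and Pgk1 at -0.91. Of 19 cholesterol synthesis genes, 13 fell and 6 were not called (15 lower adjusted over the list alone; camera adjusted p = 8.11e-08, adjusted p = 0.432 with an estimated correlation), with Hmgcs1 at -1.24. Some genes of division rose: 7 of 20 G2 and mitosis genes, with 13 not called (9 higher adjusted over the list alone), and 6 of 20 DNA replication genes, with 14 not called (8 higher adjusted over the list alone). Aurka (0.48), Ccnb2 (0.45) and E2f1 (0.66) were among them. The glycolysis, mitosis and replication lists each had camera adjusted p = 0.000195 and adjusted p = 0.632 with an estimated correlation. The lung of Rat3789 stood lowest among the lungs for the mitosis list, at a mean of 6.74 log2 CPM.

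Other lists were not called in the lung. The integrated stress list had camera adjusted p = 0.0927, with Sesn2 (0.88) and Herpud1 (0.66) rising and 17 of 19 not called (0 adjusted over the list alone). With the rat as a block it was called (adjusted p = 0.0291; 0.0153 to 0.446 over all alternatives), as it was without the lung of Rat3789 (0.0153) or the rim of Rat3877 (0.0182). Sesn2 lost its call with that block, by limma-voom and when thinned, and both genes lost theirs without the lung of Rat3877, Rat3876, Rat3875 or Rat3869 or the rim of Rat3876, Rat3875, Rat3869 or Rat3867 (adjusted p up to 0.0901 for Sesn2 and 0.0744 for Herpud1). In the mesenchymal list (camera adjusted p = 0.739), Zeb2 (0.71), Col5a1 (1.00), Sparc (0.62) and Twist1 (0.50) rose, 4 fell, including Tnc (-2.68), Itga5 and Inhba, and 8 of 16 were not called (4 higher and 4 lower adjusted over the list alone). Sparc lost its call without the lung of Rat3877, Rat3876 or Rat3875 or the rim of Rat3869 or Rat3867 (adjusted p up to 0.0679). Twist1 lost its call without any 1 library other than the lung of Rat3789 or the rim of Rat3877, and under relative log expression or upper-quartile scaling, limma-voom and edgeR (adjusted p up to 0.112). The angiogenic list (camera adjusted p = 0.739) had Angpt2 (1.23) and Angpt1 (1.56) higher, Pdgfb (-3.04), Pgf (-1.22) and Pdgfa (-0.59) lower and 9 of 14 not called (5 higher and 3 lower adjusted over the list alone). Zeb2, Col5a1, Sparc, Twist1, Angpt1, Pgf and Pdgfa were named after their values were seen, and Angpt1 was not called without the lung of Rat3877 or Rat3875 or the rim of Rat3876 or Rat3867 (adjusted p up to 0.0645).

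The host part of the lung libraries was read only to describe the tissue. Rat Sftpc, the surfactant protein of alveolar type II cells, stood between 3126 and 5676 CPM in 4 lungs and at 1.88 CPM (16 reads) in the library labelled lung from Rat3789. In that library rat Col1a1 was at 7722 CPM and Adipoq at 61.7 CPM. Without this library, 2897 mouse genes were called between lung and rim.

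**Figure D5:**
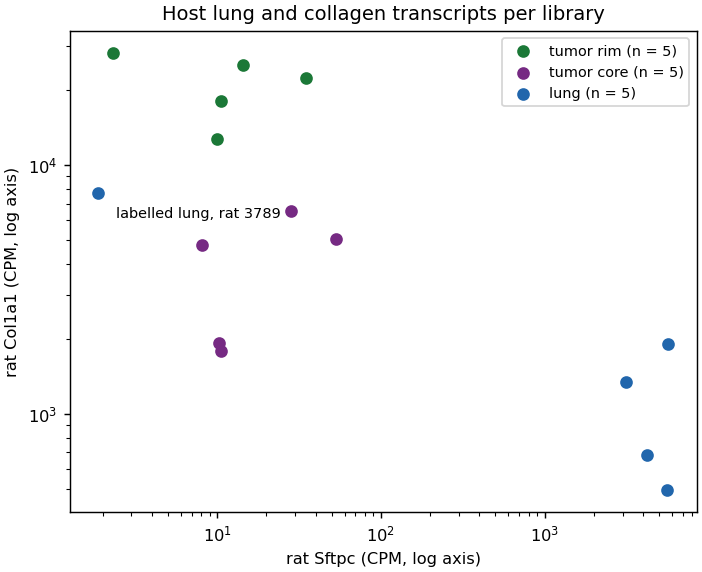
Rat Sftpc against rat Col1a1 in each rim, core and lung library, in CPM on log axes. The library labelled lung from Rat3789, at 1.88 CPM of Sftpc, lies with the tumor libraries, and the other lungs lie at 3126 CPM or above.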

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

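The tests of read number and of an exchange for the library from Rat3789, the scaling tests of the size of the differences and of genes that differ by at least 1 on the log2 scale, and the test of the mitosis list against all rat genes were chosen after the results were seen.

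The library labelled lung from Rat3789 lay far from the other lungs in the alveolar and airway list of the host, at a mean of 2.91 log2 CPM against 9.56 or more. Too few reads are argued against by its 8923328 rat reads, above the 6976025 of the shallowest other lung, and an exchange with a tumor library by the highest alveolar level among the 10 tumor libraries, 4.99. On an axis of mouse genes that runs from 0 at the rims to 1 at the other lungs, it lay at 0.872. The library thus lay within the 0.775 to 1.07 of the other lungs and outside the -0.174 to 0.487 of the rims. That argues against rim tissue. On the same axis of host genes it lay at 0.245, against 0.869 to 1.08 in the other lungs and -0.056 to 0.177 in the rims, so its host profile lay nearer to the rims, which is consistent with lung tumor tissue that held little lung parenchyma. This stays a hypothesis, as no core library was placed on either axis, so the axes do not argue against tissue of a tumor core. Single mouse genes, compared after the results were seen, argue against it in part. Postn was at 0.575 CPM against 445 to 1685 in the cores, and Mki67 at 361 against 96.8 to 200. Vegfa (34.7), Angptl7 (18.5) and, near the floor, Krt14 (0.65) lay below the cores. Mmp9, at 28.1 CPM, lay within their 11.5 to 33.2. A wrong label or an exchange with a sample outside the series was not tested.

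Among 9760 symbols tested in both species, 248 genes were higher in the core in mouse and lower in the core in rat, with median log2 differences of 1.02 and -1.40. That is above the 189 expected if the calls were independent, but so were the genes higher in both (215 against 187), lower in both (201 against 185) and lower in mouse and higher in rat (206 against 184). Rat reads counted as mouse are argued against, since they would give a median of 0.133% of the mouse core reads of these genes. Each of 3 scalings moved all 248 genes of a species by a shared amount, as the SD of their log2 differences stayed at 1.28 in mouse and 1.13 in rat. The medians kept 95.5% or more of their size in either species, so the choice among these scalings does not set differences of this size. All 248 genes kept both directions, but they were picked as called in both species, so this decides nothing. Total-count scaling moved the split of all called mouse genes to 1139 higher and 1515 lower. Single calls depend on scaling more, as 86.3% kept both calls under total-count scaling. The 30 mouse calls that ended had a median log2 difference of 0.44 before (SD 0.37) and 0.40 after (SD 0.37). Their median limma adjusted p was 0.0392 before and 0.0581 after. Why these calls and not others ended was not tested. For the 98 genes that differed by at least 1 in both species, 94.9% or more kept both calls under 3 scalings, but these genes were picked for large differences, so this decides nothing. A difference in how tumor and host cells respond in the necrotic region may account for the pattern, as an untested biological explanation.

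The G2 and mitosis list was lower in the core in mouse genes and higher in rat genes, in opposite directions in all 5 rats (mouse minus rat -1.63 on the log2 scale, SD 0.558; exact sign-flip p = 0.0625, the smallest that this test gives with 5 pairs, adjusted p = 0.113, so it cannot decide). Mouse reads counted as rat would give a median of 0.391% of the rat core reads of the list. The highest camera adjusted p of the rat list under 3 scalings was 0.000209, which decides nothing, because camera compares the list with other genes and a factor per library hardly moves it. The list median of core minus rim lay above that of all rat genes in each of the 5 rats. The gap was 0.115 to 1.05 on the log2 scale, while a factor shared by all rat genes of a library would move both alike. Camera had already called the list above other rat genes, so this is not independent of that call. Removing a trend with transcript length and GC kept 96.9% of the mouse median (-1.11 before, -1.08 after). These values argue against assignment, a shared scaling factor and, for the mouse genes, length or GC as the whole cause. Length and GC of the rat genes were not examined. Fewer dividing tumor cells and a different mix of dividing host cells in the core may explain it, which was not tested, and 32 of 100 splits of the libraries gave as small a camera p for the rat list.

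The difference of core minus rim between mouse and rat was also tested per gene with limma: 3489 of 9760 shared symbols differed, 1871 more positive in mouse and 1618 in rat, and 656 of these moved in opposite directions in all 5 rats. Among the named genes, the mouse minus rat value on the log2 scale was 10.01 for C4b, 8.62 for Postn, 7.39 for Dcn, 6.83 for Angptl7 (adjusted p = 0.000521), 4.33 for Slc6a2 and 1.10 for Vegfa. It was -5.20 for Acap1, -4.28 for Mmp9, -2.80 for Spp1, -2.49 for Sfn, -2.29 for Lamb3 and -2.23 for Mki67. For Krt14 it was -1.23 and was not called (adjusted p = 0.520). The angiopoietin-like and angiogenic list moved in opposite directions in all 5 rats (mouse minus rat 1.77, SD 0.248 over rats; exact p = 0.0625, again the smallest possible, adjusted p = 0.113, so the test cannot decide).

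In 20 of 207 groups of 5 libraries, 1 library lay far from the other 4, where chance gives about 1 in 20 groups. The rim of Rat3876 had the lowest mouse share, 65.7% against 79.6% or more. The lung of Rat3789 was lowest in mean log2 CPM for mouse G2 and mitosis genes (6.74), mouse immediate early genes (5.19), rat inflammatory genes (3.61) and rat mammary epithelium (-0.47), lowest in log2 CPM of mouse Nrcam (2.82), and highest for rat adipocyte genes (5.54). The rim of Rat3877 was lowest for mouse epithelial genes (6.05), mouse mesenchymal genes (6.72) and rat skeletal muscle genes (0.78), and for mouse Postn (2.25), Krt14 (3.91), Sfn (6.19) and Mmp13 (3.79). The remaining ones were the rim of Rat3867 for rat alveolar genes (1.03), the core of Rat3869 for rat erythroid genes (6.72, highest), the rim of Rat3869 for mouse C4b (-0.68), the lung of Rat3869 for mouse Camk1d (5.56) and the rim of Rat3876 for rat Nos2 (-1.03).

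In material that enters no main comparison, rat Sftpc had a median of 4202 CPM in the lungs. The 4T1 pellet held 3120 reads of rat Myh4, a fast muscle myosin, against 1822919 and 1371775 in the gland libraries, with Acta1 at 1212 and Ckm at 662 reads. Myh4, Acta1 and Ckm took 1.46, 0.569 and 0.311% of the rat reads of the pellet. In gland library 2 the same genes took 6.41, 2.51 and 1.36% of the rat reads, nearly the same proportions to each other as in the pellet. The source of the muscle reads in the pellet was not tested, so the rat share of the pellet is not shown to be assignment error alone.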

How the results depend on the processing

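The alternatives with edgeR, an added 1 CPM, total-count scaling, transcript length and GC, complete rats only, and Rat3876 and Rat3877 left out together were chosen after seeing the data. Between core and rim, leaving out 1 rat gave 1260 to 2422 mouse genes (1260 without Rat3875, 1360 without Rat3867, against 2585) with 8 to 13 lists, and 3805 to 4763 rat genes with 11 to 16 lists. Leaving out Rat3876 and Rat3877 together gave 1857 mouse genes and 3392 rat genes, against 5092. Between lung and rim, leaving out 1 library gave 1589 to 3397 genes (1589 without the lung of Rat3877, 3397 without the rim of Rat3877) with 7 to 9 lists. These fits hold fewer samples. Of the 2585 mouse genes, 47.5% kept their call and direction without Rat3875, the lowest share of any setting. Without the block by rat, 2630 mouse and 5049 rat genes were called, and with it 2431 between lung and rim (2463 in complete rats). Of the 2603 genes called between lung and rim, 75.8% kept their call and direction with the block. The pairing changed no call of a list or named gene except those given in the report, mt-Nd2 between lung and rim (called with the block, adjusted p = 0.0499) and the interferon list between lung and rim in complete rats (adjusted p = 0.0420; up to 0.964 over all alternatives). On the recovered reads edgeR called 2638, 4752 and 2655 genes and DESeq2 3142, 4398 and 3602 in the 3 comparisons in order, and limma-voom 2596, 5237 and 2520. No setting in the 3 comparisons called a gene in the opposite direction, and the largest shift of the median of all genes was 0.05 on the log2 scale. Of the values of named genes under the alternatives, 3614 stayed on their side of the threshold, 150 lost a call and 20 gained one. Another 3 changed direction without a call in either setting, and 0 changed direction with one.

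The core minus rim difference in mouse share was 5.37 to 9.51 points with 1 rat left out, and 8.44 in the unpaired test without the block (exact p = 0.00794). The lung minus rim difference was -8.69 to -4.44, called without Rat3876 (-8.69, exact p = 0.0286) and smallest without Rat3877 (-4.44, exact p = 0.371); paired over 4 rats it was -6.96 (exact p = 0.25). Reads on genes of the other species made up 1.84, 2.02 and 0.715% of gland library 1, gland library 2 and the pellet without mitochondrially encoded genes. Over shared symbols they made up 1.75, 1.88 and 0.631%. The cause of these changes was not tested. Thinned to the lowest total, 4813 rat genes were called.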

Other observations

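The tests of all splits were fixed before the results were seen, and the genes Casp4, Gsdme, Bak1 and Mlkl and other members given without a value were named after their values were seen.

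In the 4T1 cells of the core, genes of cell death moved both ways: 3 were higher (Fas, 1.45, Casp4 and Gsdme, an effector of lytic death), 5 lower, including the cell cycle inhibitor Cdkn1a (-1.26), Bak1 and Mlkl, and 9 of 17 not called (3 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.957, median 0.14 with a downward test). Immediate early genes divided as well, with Dusp1 (2.42), Fos, Ier3, Klf4 and Nr4a1 higher, Dusp6 (-0.56), Dusp5 and Egr2 lower and 9 of 17 not called (6 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.0968). That list was called without Rat3877 (adjusted p = 0.00659), without Rat3876 (0.0410) and without both (0.000376), with a range of 0.000376 to 0.219 over all alternatives. Matrix proteases were not called as a list (camera adjusted p = 0.763; median 0.09, mean -0.20): 5 were higher, including Plat, Ctsl, Ctsb and Mmp2 (1.80), 4 lower, namely Plau (-1.89), Mmp9, Mmp10 and Mmp13 (-1.85), and 8 of 17 not called (6 higher and 4 lower adjusted over the list alone). Mmp2 and Mmp13 lost their calls without Rat3876, Rat3875, Rat3869 or Rat3867 (adjusted p up to 0.0748 and 0.0798). Of 12 mitochondrially encoded genes only mt-Nd1 was called (0.40; camera adjusted p = 0.148; 0 adjusted over the list alone), and not without Rat3876, Rat3875 or Rat3867 (adjusted p up to 0.116) or without Rat3876 and Rat3877 together (0.0768); the list was called with a length and GC trend removed (0.0425). Of 4 alveolar genes kept as a species check, Napsa was called (1.17, adjusted p = 0.0488; up to 0.275 over all alternatives, and not called in 15 of 19 of them, including each that leaves out 1 rat), and the list was not (camera adjusted p = 0.0970; 2 higher adjusted over the list alone) except with no filter (0.0498).

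In the host, adipocyte genes were not called as a list (camera adjusted p = 0.0615), with Cfd (-3.56), Lpl (-2.20) and Plin4 lower and 7 of 10 not called (3 lower adjusted over the list alone). They were called without Rat3875 (adjusted p = 0.0279), Rat3869 (0.0251) or Rat3867 (0.0188), by limma-voom (0.00937), with no filter (0.0420), with a mean count of at least 10 (0.0450) and when thinned (0.0477), with a range of 0.00937 to 0.499 over all alternatives. Dendritic cell genes (camera adjusted p = 0.451) had Itgax higher (1.20), Zbtb46 lower (-1.24) and 11 of 13 not called (1 higher and 1 lower adjusted over the list alone); Zbtb46 was not called without Rat3877 or Rat3867 (adjusted p up to 0.0573). Lymphocyte genes (0.633) had Lck higher (0.98), Cd8a lower (-2.13) and 3 of 5 not called (1 higher and 1 lower adjusted over the list alone). Platelet genes (0.466) had Itgb3 (-0.74) and Pf4 (-0.93) lower and 2 of 4 not called (2 lower adjusted over the list alone), and Pf4 was not called without Rat3876 (adjusted p = 0.0689) or without Rat3876 and Rat3877 together (0.0994). Coagulation genes (0.466) had F13a1, Plau (1.58) and Anxa2 higher, Plat (-2.61), Tfpi (-1.18), F3, F10 and Procr lower and 7 of 15 not called (3 higher and 5 lower adjusted over the list alone). Alveolar genes (0.0850) had Napsa (1.77) and Hopx (0.55) higher and 8 of 10 not called (2 higher adjusted over the list alone); the list was called without Rat3877 (adjusted p = 0.0312) or Rat3869 (0.0126), and Hopx was not called without Rat3876, Rat3869 or Rat3867 (up to 0.0581) or without Rat3876 and Rat3877 together (0.0587). Erythroid (0.487), mammary epithelium (0.162) and skeletal muscle genes (0.466) had 0 called members, also adjusted over the list alone. The last 2 lists were called without Rat3869 (adjusted p = 0.0199 each), and mammary epithelium also by limma-voom (0.00189). Krt15 of the mammary list was called lower by DESeq2 (adjusted p = 0.0251), limma-voom (0.00944), edgeR (0.0195) and without Rat3869 (0.0109). Tnni2 of the muscle list was called higher by DESeq2 (0.0411) and limma-voom (0.0310). Myh4 (0.00585) and the alveolar gene Sftpc (0.0313) were called higher without Rat3869, and both were named after their values were seen. Mitochondrially encoded genes (0.903) had Mt-co1 (0.52) and Mt-co3 (0.42) higher and 11 of 13 not called (0 adjusted over the list alone), and these calls ended without any 1 of the 5 rats (adjusted p up to 0.111 and 0.136), without Rat3876 and Rat3877 together, with no filter and with an added 1 CPM, and that of Mt-co3 also when thinned.

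In 4T1 cells of the lung, inflammatory genes (camera adjusted p = 0.739) had Ccl2 higher (2.31), Nfkbiz (33.0 CPM in the lung and 67.7 in the rim), Tnfaip3 (-0.94), Lif and Csf3 lower and 6 of 11 not called (2 higher and 4 lower adjusted over the list alone). Ccl2 was not called without the lung of Rat3877, Rat3876, Rat3875 or Rat3869 or the rim of Rat3876 or Rat3869 (adjusted p up to 0.103). Immediate early genes (0.739) had Fosl1 (1.45), Dusp1 and Nr4a1 higher, Egr2 (-1.36), Junb, Ier3 and Dusp6 lower and 10 of 17 not called (4 higher and 4 lower adjusted over the list alone). Of 11 heat shock genes (0.134) Hsph1 was higher (0.73; 4 higher adjusted over the list alone), of 19 interferon genes (0.739) Zbp1 was lower (-1.09; 0 adjusted over the list alone), and of 17 cell death genes (0.95) Bax was higher (0.39) and Bcl2l11 lower (-0.48; 1 and 1 adjusted over the list alone). Each of these 4 genes was not called without the lung of Rat3877. Hsph1 also lost its call without the lung of Rat3876, Rat3869 or Rat3789, without the rim of Rat3875, Rat3869 or Rat3867 and by edgeR (adjusted p up to 0.0893). Zbp1 did so without the lung of Rat3875 or the rim of Rat3876, Rat3869 or Rat3867 (up to 0.0697), Bcl2l11 without the lung of Rat3876, Rat3875 or Rat3869 or the rim of Rat3869 or Rat3867 (up to 0.0623), and Bax under no other setting (0.0573). The heat shock list was called without the rim of Rat3877 (adjusted p = 0.0278). Of 12 mitochondrially encoded genes (0.318) 0 were called by limma, also adjusted over the list alone, with mt-Nd2 nearest (0.35, adjusted p = 0.0729); it was called with the rat as a block, in complete rats, under total-count scaling and without the rim of Rat3876 (adjusted p down to 0.0486).

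Other splits of the 10 libraries into 5 and 5 were counted to ask whether chance gives as many calls. Of 100 splits, the real one included, 1 called as many mouse genes between core and rim (2585, highest other 0), 1 as many rat genes (5092, highest other 0) and 1 as many between lung and rim (2603, highest other 1367). This excludes chance for these counts only among splits that mostly ignore the rat, while core and rim share all 5 rats and 4 lungs share a rat with a rim. For the number of lists called chance is not excluded: 5 of 100 splits gave as many for mouse genes of core and rim (12, highest other 13), 37 for rat genes (12, highest other 16) and 22 for lung and rim (7, highest other 10). Of the called lists, fewer than 5 of 100 splits gave as small a camera p for mesenchymal (3) and angiogenic genes (4) of mouse in the core, for fibroblast (1), glycolysis (1) and hypoxia genes (3) of rat, and for epithelial genes in the lung (1). For the other called lists chance is not excluded: in mouse core and rim, inflammatory (56), glycolysis (44), interferon (43), heat shock (37), integrated stress (29), epithelial (23), hypoxia (13), DNA replication (12), G2 and mitosis (7) and cholesterol synthesis (5); in rat, inflammatory (43), mast cell (41), neutrophil (39), G2 and mitosis (32), pericyte (28), heat shock (14), interferon (8), matrix protease (8) and lymphatic (7); in the lung, G2 and mitosis (38), DNA replication (31), glycolysis (23), hypoxia (18), cholesterol synthesis (16) and matrix protease (5). Among the 16 splits that part every core from the rim of its rat, the highest other list counts were 11 for mouse and 15 for rat, and 6 of the 16 gave as many rat lists; the highest other gene count was 0 for both. These 16 are too few for a share under 0.05. Some of the 100 splits kept 4 of the 5 libraries of a group together and so carry part of the real difference. The shares of single lists were also not corrected for the number of lists. So they do not rank the lists, and a share under 5 of 100 does not exclude chance for its list either.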
